A study of Mus musculus with 4 samples.

How the data were processed

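RNA immunoprecipitation followed by sequencing was carried out on mouse brown adipose tissue, with RNA recovered by an antibody against FAM172A (IP) or by control immunoglobulin (IgG). Per the labels' protocols, ribosomal RNA was depleted and directional libraries were prepared. 4 libraries were used as 2 pairs, each with 1 IP and 1 IgG library. The pairing comes from the sample titles and from the tables, of which there is 1 per pair, each normalized separately. The columns of 1 table carry the WT4 titles. The columns of the other name only IP and IgG, so that the libraries titled cold belong to it by elimination only, and no column name says so. It is called the first pair here. The labels give the cold protocol for the libraries titled cold and no protocol for the WT4 libraries. Nothing in the labels says that the pairs came from separate animals. The p-values therefore measure only spread between these samples, pooled across genes, which may be technical. All columns of sample values were used.

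Per the submitters' processing notes, cutadapt 1.9.3, HISAT2, Cufflinks and Cuffdiff were used with the mm10 build, and no role or order is given for them. The annotation release is not given in the sources used here. Both tables listed 22564 genes with 22481 symbols. The deposited estimated counts were whole multiples of 1 step per library for most genes, which was 0.926 and 1.09 in the first pair's IP and IgG columns and 2.71 in the WT4 IgG column, and 0.731 in the WT4 IP column. Dividing by the step gave fragments, and between 94.5% and 97.8% of values above 0 lay within 0.05 of a whole number. Fragments were rounded to whole numbers before any count test. The authors deposited FPKM in separate columns, which served as an alternative. The locus column gives overlapping genes 1 merged interval, and 25.9% of symbols shared a locus with another gene. Such genes, and genes with near-identical copies, have uncertain counts.

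The main value, called scaled CPM here, was the deposited scaled count divided by the mean scaled total of its pair and multiplied by 1000000. The log2 ratio of IP over IgG was taken within a pair after adding 1, which shrinks the ratio of low genes. It does not keep genes with few fragments from passing a 2-fold line. Cd3g, for example, had a log2 ratio of 1.23 in the WT4 pair on 2 IP and 0 IgG fragments. Genes with a mean over the 4 libraries of at least 1 scaled CPM were kept (16218 genes), and rows of 1 symbol were summed. A 2-fold line was used for counts within a pair, where 1 library per group allows no test. Across both pairs, edgeR's quasi-likelihood test was run with the pair as a block, library sizes from the authors' scaling and Benjamini-Hochberg adjustment. This left 1 residual degree of freedom per gene. The fitted prior degrees of freedom were infinite, so the spread was pooled across genes and a gene's own spread had no weight. The design fixed before the data were examined named limma on log2 values, and edgeR if the files held counts. Estimated counts were found, so edgeR was used. The CPM scale and the use of the authors' scaling in place of TMM factors were settled after the files had been opened and after both scalings had been tried with edgeR, each giving 1 call. An exact permutation of 2 against 2 libraries cannot go below p = 0.333, two-sided.

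Of the 28 gene lists fixed before the data were examined, each was described by its median log2 ratio per pair and the percentile of that median among 10000 random lists of the same size matched in 20 strata of mean level. The named genes were Fam172a, Bdh1 and the ketone body list, the 10 highest and 10 lowest mean ratios among genes at least 2-fold the same way in both pairs, and up to 4 such members of each list, or its 2 most abundant members where it had none. Enrichment of the tables' own pathway and gene ontology terms with 10 to 500 genes was tested with a one-sided hypergeometric test against the tested genes that carry a term. Gene coordinates are 1-based and from GENCODE vM21 on GRCm38, the assembly that mm10 names, matched by Ensembl identifier. Zc3h11a and Hist1h3d had no match there. A few genes that the rule for named genes takes are not reported here.

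Depth differed between the libraries but did not alone set how many genes were detected. The libraries held 6633653 and 5587294 fragments in the first pair (IP and IgG) and 1631881 and 360369 in the WT4 pair. For a gene at 0 in a library, a floor of 3 fragments per library was used to bound a fold. Floors and intervals cover counting error only, since fragments without molecular identifiers are not independent molecules.

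The procedures were tested on simulated data. In 10 simulations of IP against IgG across both pairs, on the real means, library sizes and fitted dispersion (a median of 15020 genes with counts), edgeR recovered 2.60% of 4-fold changes and 61.3% of 64-fold changes, and 5.75% of its calls were unchanged genes. At a lower simulated dispersion (0.1 times the fitted one) it recovered 60.0% of 4-fold changes and 99.0% of 64-fold changes. Changes were planted only in genes with a mean of at least 10 scaled CPM. Recovery at lower genes, such as Bdh1 with a mean of 6.24, was not measured. For the list percentiles, a first check with a single simulated list of the highest genes and no effect lay in the top 2.5% of random lists. It was replaced by 300 simulated lists of each kind among 4000 genes. Of lists of random genes with no effect, 3.33% lay in the top 2.5% of random lists and 2.33% in the bottom 2.5%. Lists made of the highest genes by level had a mean percentile of 57.9, with 4.67% in the top 2.5%, so matching in strata slightly favours such lists. Drawing each member from the 100 genes nearest in level gave a mean percentile of 52.8 for them and was added as an alternative.

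The alternatives were another pseudocount (0.1), median-centred ratios, a minimum of 5 scaled CPM or none, quantile normalization, a 4-fold line, the highest row of each symbol, fits without the pair block, DESeq2, limma with and without trend, and leaving out each library in turn. Chosen after the data were seen were TMM factors, total fragments, the FPKM columns, limma on log2(FPKM + 1), only genes detected in all 4 libraries, a minimum of 100 scaled CPM for the correlation, and the nearest-level draw. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.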

Results

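The series used RNA immunoprecipitation sequencing to look for transcripts bound by FAM172A in the brown adipose tissue of mice, a fat depot that burns lipid to make heat. The labels name cold exposure for 1 pair of libraries and give no protocol for the other, WT4. RNA recovered with the FAM172A antibody (IP) was compared with RNA recovered with IgG in 2 pairs of libraries, the first pair and the WT4 pair. The first pair held 6633653 IP and 5587294 IgG fragments, and the WT4 pair 1631881 IP and 360369 IgG fragments. Fragments were found on 11584 and 13391 genes in the first pair, and on 17693 and 9310 genes in the WT4 IP and IgG libraries. Mitochondrially encoded genes took 9.28% and 7.07% of fragments in the first pair's IP and IgG libraries, and 13.7% and 9.72% in those of the WT4 pair.

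The first question was whether Bdh1 RNA, named in the series title and coding for the mitochondrial enzyme that interconverts acetoacetate and beta-hydroxybutyrate, was recovered with the antibody. Bdh1 (ENSMUSG00000046598, chromosome 16, 31422280 to 31458901, plus strand) had 27 fragments in the first IP library and 31 in the WT4 IP library, and was listed at 0 in both IgG libraries. Abundant genes were listed at 0 as well: of 812 genes over 200 scaled CPM in the other libraries, 15 were at 0 in the WT4 IgG library. Against a floor of 3 fragments in each IgG library it was at least 7.66-fold higher in IP in the first pair and at least 2.79-fold higher in the WT4 pair, bounds that cover counting error only. In the first IP library genes of 1 to 10 scaled CPM had an estimated 50.2 fragments per molecule, more than Bdh1's 27. That estimate rose with level, from 43.2 at 1 to 5 scaled CPM to 169 at 100 to 200. It is no fixed number per molecule, so it does not give a count of Bdh1 molecules. Bdh1's log2 ratio was 2.35 and 4.45, with a mean of 3.40 ± 1.49 (SD, n = 2 pairs). It did not pass the test across both pairs (edgeR quasi-likelihood with Benjamini-Hochberg adjustment, adjusted p = 1.0, unadjusted p = 0.328). Fam172a itself (ENSMUSG00000064138, chromosome 13, 77702033 to 78166235, plus strand) had 141 IP and 135 IgG fragments in the first pair and 99 and 24 in the WT4 pair, for log2 ratios of -0.16 and 0.15. The table gives Fam172a a locus shared with another gene.

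On scaled CPM, Bdh1 of the 9 tested ketone body genes was at least 2-fold higher in IP in both pairs, and none was 2-fold lower in both. None passed the test over all genes or adjusted over the list alone (edgeR, smallest adjusted p = 0.275). Oxct1, the enzyme that activates acetoacetate for oxidation, had 892 IP and 451 IgG fragments in the first pair and 110 and 0 in the WT4 pair. In FPKM Oxct1 stood at 180 in IP and 29.8 in IgG, then at 37.1 and 5.4e-06. On that measure it too was over 2-fold higher in both pairs. Acat1 had log2 ratios of 0.34 and 0.18, Aacs of 0.22 and 0.81, and the monocarboxylate carrier Slc16a1 of 0.40 and 0.24. In FPKM Acat1 was lower in IP in the first pair (63.7 and 117) and higher in the WT4 pair (70.7 and 23.5). Slc16a6 was found in the WT4 IP library alone (11 fragments), and Slc16a7 had 18 and 19 fragments, then 7 and 0. The list's median log2 ratio was 0.34 in the first pair (percentile 96.2 among matched lists) and 2.51 in the WT4 pair (percentile 90.6).

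**Figure D1:**
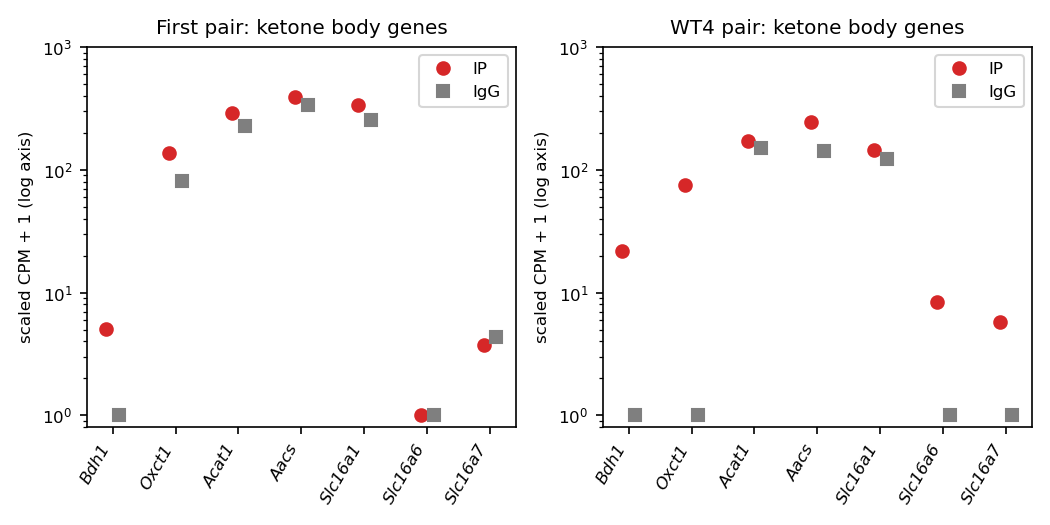
Scaled CPM plus 1 (log axis) of 7 tested ketone body genes in the IP (circles) and IgG (squares) library of each pair; each point is 1 library. Bdh1 and Slc16a6 lie at 0 fragments in both IgG libraries, and Oxct1 and Slc16a7 in the WT4 IgG library.

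The next question was which transcripts were recovered more with the antibody in each pair. In the first pair 2157 of 16218 genes were at least 2-fold higher in IP and 4364 at least 2-fold lower. In the WT4 pair 8370 were higher and 3125 lower, and 78.5% of those higher had 0 fragments in the WT4 IgG library. The median log2 ratio was -0.03 in the first pair and 1.18 in the WT4 pair. With each pair centred on its median, the share of higher among the changed genes of the WT4 pair went from 72.8% to 51.9% (6475 higher and 5997 lower). In both pairs 1166 genes were higher, against 1113 for independent lists of those sizes, and 852 were lower, against 841. Among genes detected in all 4 libraries 105 were higher in both, against 166, and 325 lower, against 271. Of the genes higher in both, 1046 had 0 fragments in the WT4 IgG library. The genes that went opposite ways in the 2 pairs numbered 2812, against 2668 for independent lists, and those that went the same way 2018, against 1954. When centred these were 2605 and 2476. Across genes, which are not independent replicates, the log2 ratios of the 2 pairs had a Pearson r of -0.019 and a Spearman rho of -0.008. No pathway or gene ontology term was enriched among the genes higher or lower in both pairs (hypergeometric test, smallest adjusted p = 0.172).

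Among the 10 genes with the highest mean log2 ratio, 8 had 0 fragments in both IgG libraries. Cmtm6, a membrane protein that stabilises PD-L1, had 579 IP fragments in the first pair and 47 in the WT4 pair. Nfkb2, a subunit of NF-kappa-B, had 215 and 51, Jph4, a junctophilin, 183 and 52, Asrgl1 294 and 27, the complement gene C4b 282 and 28, and Ccdc61 182 and 41. Gm20716 had 396 and 132 and Zc3h11a 219 and 75. E4f1 had 434 IP fragments against 1, then 111 against 1. Gm20716, Zc3h11a, Nfkb2 and mt-Atp6 share a listed locus with other genes and are uncertain. The 10 lowest genes all had 0 fragments in the first IP library, and 8 had 0 in the WT4 IP library too. Tst, a mitochondrial sulfurtransferase, had 31 IgG fragments in the first pair and 29 in the WT4 pair, Enoph1 of methionine salvage 58 and 24, the ion channel gene Hcn4 53 and 18, and Ebpl 34 and 26. Tnfaip8l1 had 66 IgG fragments in the first pair, and 3 IP against 44 IgG fragments in the WT4 pair. Mypop had 157, then 9 against 36. Mfrp, Gm20503, B4galnt3 and Itgb2l, with 0 IP fragments in both pairs, lie on different chromosomes. Each shares its listed locus with other genes, as does Mypop.

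Across both pairs, mt-Atp6 was the 1 gene past the test, and it was higher in IP (edgeR quasi-likelihood, log2 fold change 5.40, adjusted p = 6.2e-10, higher in both pairs), and 0 genes were lower. It encodes a subunit of the mitochondrial ATP synthase (chromosome M, 7927 to 8607, plus strand). It had 66933 IP and 2381 IgG fragments in the first pair and 611 and 1 in the WT4 pair. With the spread pooled across genes, the p-value does not measure how closely this gene's ratios matched between the pairs. At an unadjusted p under 0.05 there were 139 genes higher and 96 lower, a balance that moved with scaling (35 and 350 when centred, 153 and 33 with TMM factors). DESeq2 called 3 higher and 0 lower, and limma 12 and 1. Without the pair block mt-Atp6 did not pass (edgeR, adjusted p = 0.281). Leaving out 1 of the 4 libraries needs that fit, and gave adjusted p from 0.567 to 1.0 with log2 fold changes from 0.94 to 11.01. Its locus holds 6 listed genes and it has a near-identical nuclear copy, so its count is uncertain. mt-Nd6, the light-strand complex I gene, was 2-fold higher in both pairs, at 1.61 and 1.16, and did not pass the test. Its WT4 ratio lay below that pair's median of 1.18 over all genes, though above the 0.46 of genes of at least 100 scaled CPM. It was no longer 2-fold higher in both pairs when centred (mean 0.81), with quantile normalization, with total fragments or in FPKM. The 12 tested mitochondrially encoded genes had medians of 0.20 and 1.05 (percentiles 89.5 and 95.2), and 1 was called adjusted over the list alone.

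Genes of brown fat function showed median ratios near 0 in the first pair. In the WT4 pair the median was 1.18 over all genes but 0.46 among genes of at least 100 scaled CPM. List medians there are therefore to be read with the percentiles among lists matched on level. The thermogenic, lipolysis and lipogenesis medians lay below 1.18, and of these only that of lipogenesis lay below 0.46. Of 28 thermogenic and brown adipocyte genes, 0 were 2-fold the same way in both pairs, and the medians were 0.12 and 0.98 (percentiles 92.0 and 97.4). Ucp1, the uncoupling protein of heat production, had 38953 IP and 32123 IgG fragments in the first pair and 3708 and 527 in the WT4 pair, for log2 ratios of 0.05 and 0.92. Acot11 had 0.37 and -0.14. Fatty acid uptake and oxidation had 28 genes with medians of 0.05 and 1.37 (percentiles 72.2 and 100), with Lpl at 0.35 and -0.22 and Fabp4 at 0.09 and 1.71. Lipolysis and lipid droplet genes had 12 members with medians of -0.06 and 0.71 (percentiles 41.8 and 77.8), with Pnpla2 at 0.13 and 0.30 and Mgll at -0.13 and 1.03. Lipogenesis had 20 genes with medians of 0.15 and 0.41 (percentiles 88.4 and 31.4), with Scd1 at 0.72 and 0.31 and Fasn at -0.07 and 0.43. Of 13 adipocyte markers, Nnat was 2-fold higher in both pairs except with quantile normalization, and the medians were -0.23 and 1.71 (percentiles 27.3 and 95.8). Nnat, which shares a listed locus, had 38 IP and 7 IgG fragments in the first pair. In the WT4 pair it had 13 and 0, at least 1.17-fold against the floor, so a 2-fold increase is not bounded there. None of the genes of these lists passed the test over all genes or over its list alone.

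Nuclear-encoded respiratory chain genes (34 tested) had medians of 0.01 and 1.248 (percentiles 73.6 and 99.96), with Atp5a1 at 0.16 and -0.18 and Atp5b at 0.18 and 0.59. The 18 tricarboxylic acid cycle genes had 0.09 and 1.247 (percentiles 76.0 and 99.7), with Pdk4 at 0.45 and 1.06. The 33 cytosolic ribosomal protein genes had -0.20 and 2.06 (percentiles 32.3 and 99.95), and Rps23 was 2-fold higher in both pairs. Glycolysis (18 genes) had 0.11 and 1.04 (percentiles 82.9 and 97.4), and 2 of its genes, Ldha and Pgk1, passed edgeR's test adjusted over the list alone (smallest adjusted p = 0.0439), though none did over all genes. Ldha had log2 ratios of 0.17 and 4.21, with 8 IgG fragments in the WT4 pair, and Pgk1 of 0.77 and 6.35, with 120 IP and 0 IgG fragments there. Gapdh was 2-fold higher in both pairs and is uncertain because of its many pseudogenes. In the WT4 pair Gapdh had 16 IP and 0 IgG fragments, at least 1.44-fold against the floor. Adrenergic and cAMP signalling (18 genes) had 0.06 and 0.89 (percentiles 76.7 and 90.7), with Gnas at 0.00 and 0.49 and Prkar2b at 0.46 and 0.70. In that list Adcy6 passed edgeR's test adjusted over the list alone (adjusted p = 0.0296), with log2 ratios of -0.03 and 8.27, the latter from 457 IP and 0 IgG fragments in the WT4 pair, at 387, 396 and 308 scaled CPM in the other 3 libraries. Insulin and growth factor signalling (18 genes) had -0.34 and 0.97 (percentiles 9.89 and 94.9), and Igf1 was 2-fold lower in both pairs, at -1.27 and -1.89, but its mean ratio turned positive in FPKM (0.36). No gene of the respiratory chain, tricarboxylic acid cycle, ribosomal protein and insulin lists passed edgeR's test over all genes or over its list alone.

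RNA-binding and nuclear lists came next. The 31 splicing factors and chromatin partners had medians of -0.07 and 0.90 (percentiles 40.5 and 96.5), with Hnrnpu at 0.16 and 0.67 and Hnrnpa2b1 at 0.12 and 0.84. Of 14 small RNA pathway genes, Xpo5 (1.95 and 4.87) and Prkra (1.32 and 3.92) were 2-fold higher in both pairs, and the medians were -0.57 and 0.56 (percentiles 5.47 and 60.2). The locus of Xpo5 holds 39 listed genes, so its count is uncertain. Prkra had 21 IP and 0 IgG fragments in the WT4 pair, at least 1.89-fold against the floor. The 12 replication-dependent histone genes had -1.94 and 2.84 (percentiles 0.61 and 67.4). Hist1h3d and Hist1h1b were 2-fold lower and Hist1h4h 2-fold higher in both pairs, Hist1h1b not so with quantile normalization, and counts of these near-identical genes are uncertain. In the WT4 pair Hist1h4h had 18 IP and 0 IgG fragments, at least 1.62-fold against the floor. Of the nuclear retained noncoding RNAs only Snhg11 was tested, with -2.91 and -1.06 (percentiles 6.60 and 28.6), short of 2-fold in a pair with TMM factors and in FPKM, and 0 small structured RNAs were. Heat shock and immediate early genes (18) had -0.49 and 0.92 (percentiles 8.25 and 71.2). Hspa1b was 2-fold higher and its near-copy Hspa1a 2-fold lower in both pairs, the latter not so when centred, with quantile normalization, with TMM factors or in FPKM, so both are uncertain. No gene of these RNA-binding, nuclear and heat shock lists passed edgeR's test over all genes or over its list alone.

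Markers of other cell types did not move alike. The 12 endothelial genes had medians of -1.29 and 0.74 (percentiles 0.00 and 80.8), and 9 were 2-fold lower in IP in the first pair. Tie1, an endothelial receptor, had 313 IP and 895 IgG fragments in the first pair and 200 and 125 in the WT4 pair, 2-fold lower in both but not with TMM factors. The 8 Schwann cell and neuron genes had -1.86 and -0.31 (percentiles 1.98 and 15.5), with Sox10 and Snap25 2-fold lower in both pairs, but not in FPKM, nor Sox10 with quantile normalization or Snap25 with TMM factors. The 20 skeletal muscle genes had 0.32 and 0.49 (percentiles 99.3 and 46.7), with Tnnc1 and Tnni1 2-fold higher in both, but not when centred or with quantile normalization. Tnnc1 shares a listed locus with another gene. In the WT4 pair Tnnc1 had 20 IP fragments and 1 IgG fragment, and Tnni1 4 and 0, at least 0.36-fold against the floor, so no increase of Tnni1 is bounded there. Of 13 macrophage genes, 4 were 2-fold higher and 3 lower in both pairs, with medians of 0.00 and 1.89 (percentiles 69.6 and 28.8). The first-pair median was exactly 0, the ratio of a gene with 0 fragments in both libraries. It is no measure of equal recovery. Cd68 had 108 and 0 fragments, then 7 and 0 (at least 0.63-fold against the floor), and left the 2-fold line with quantile normalization, as Itgam did there and in FPKM, while Cd14 had 0 and 36, then 15 and 30, Ms4a7 0 and 74, then 19 and 19, and Itgam 0 and 10, then 6 and 24. Fibroblast and preadipocyte genes (13) had -0.54 and 2.09 (percentiles 15.1 and 88.5), with Dpp4 2-fold lower in both. Vascular smooth muscle and pericyte genes (9) had -0.37 and 1.26 (percentiles 14.02 and 90.5), with Tagln, which shares a listed locus, 2-fold higher in both. Blood and erythroid genes (7) had -0.27 and 2.95 (percentiles 40.8 and 86.8), with Hba-a2 at -0.77 and 3.29 and Hbb-bs at -1.68 and 4.84. The 7 lymphocyte genes had 0.00, again exactly 0, and 1.23 (percentiles 66.7 and 14.01). The 4 liver genes had -0.02 and 0.37 (percentiles 55.1 and 25.2), with Ttr at -0.56 and -2.86 and Trf at 0.11 and 3.56. Cd3g, a lymphocyte gene, had 35 IP and 0 IgG fragments in the first pair and 2 and 0 in the WT4 pair, too few there to bound a fold. None of these genes passed the test over all genes or its list alone.

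**Figure D2:**
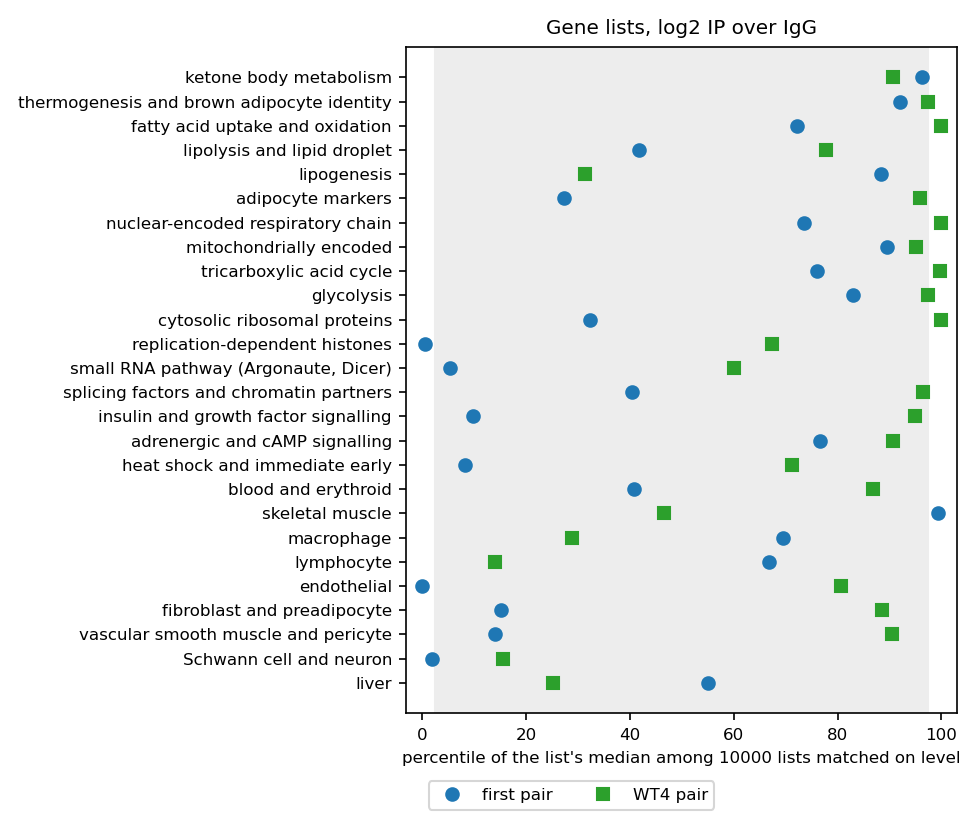
Percentile of each gene list's median log2 IP over IgG among 10000 lists matched on level, in the first pair (circles) and the WT4 pair (squares), for lists with at least 4 tested genes; grey marks the central 95%. Fatty acid oxidation, respiratory chain, tricarboxylic acid cycle and ribosomal protein lists lie above the grey band in the WT4 pair, and in the first pair skeletal muscle lies above it and histones, endothelial and Schwann cell genes below it.

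The libraries differed in how many genes had no fragment at a given level. Among genes of 20 to 50 scaled CPM in the other 3 libraries, 35.3% had 0 fragments in the WT4 IgG library, 17.3% in the first IP library, 10.1% in the first IgG library and 1.14% in the WT4 IP library. Levels correlated across genes at r 0.825 between IP and IgG of the first pair, 0.780 between the first IgG and the WT4 IP library, 0.738 between the IP libraries, 0.538 between IP and IgG of the WT4 pair and 0.455 between the IgG libraries. The tables were normalized separately, which affects levels set across them.

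**Figure D3:**
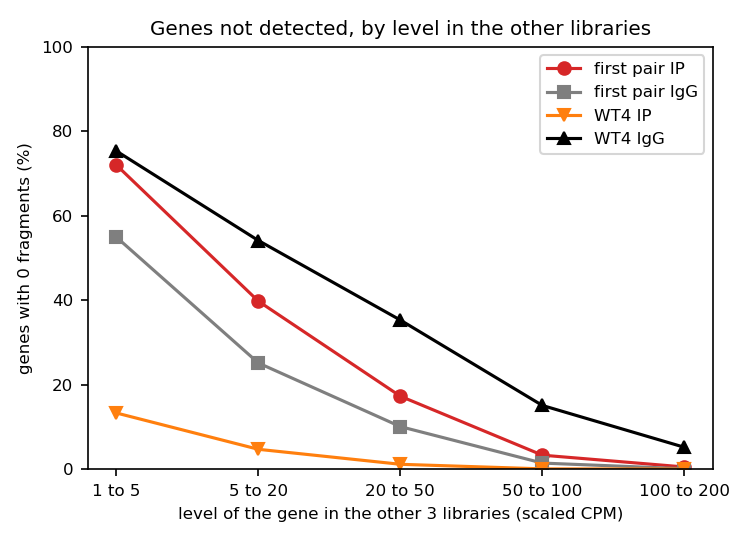
Share of genes with 0 fragments (y axis, percent) in each of the 4 libraries by the gene's level in the other 3 (x axis, scaled CPM). The WT4 IgG library lies highest at every level, with 35.3% at 20 to 50 scaled CPM.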

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

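Of the tests here, TMM factors, total fragments, the FPKM columns, limma on log2(FPKM + 1), genes detected in all 4 libraries, the minimum of 100 scaled CPM and the nearest-level draw were chosen after the data were seen. With a 4-fold line the first pair had 1064 higher and 2428 lower genes, the WT4 pair 1633 lower, and both pairs 443 higher and 253 lower. With only genes detected in all 4 libraries, which leaves fewer genes, the first pair had 684 higher and 1281 lower, the WT4 pair 1693 and 1474, and both pairs 105 and 325, against 166 and 271 for independent lists. Genes higher in both also fell below independence with quantile normalization (897 against 931), with no minimum (1178 against 1180) and at a minimum of 100 scaled CPM (11 against 15.6), and genes lower in both when centred (1554 against 1590), with total fragments (990 against 994) and in FPKM (684 against 750). A minimum of 5 scaled CPM gave 5292 higher in the WT4 pair and 749 higher in both. Quantile normalization gave 5374 higher in the WT4 pair. Centring gave 5997 lower in the WT4 pair and 1554 lower in both. Leaving out a library leaves 1 complete pair, whose counts range from 2157 to 8370 higher and from 3125 to 4364 lower. Between pairs, Pearson's r lay between -0.040 and -0.008 under the alternatives run, and Spearman's rho between -0.0197 and 0.0107.

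For the test across both pairs (1 higher, 0 lower), the pair block mattered: with no replicate block edgeR called 0 higher, and limma without it 3 higher. DESeq2 called 3 higher, limma 12 higher and 1 lower, limma with a pseudocount of 0.1 18 and 2, limma on FPKM 3 and 1, and limma without trend or with quantile normalization 0 higher. A minimum of 5 scaled CPM and centring each added 1 lower. Leaving out each library in turn, with the fit that pools the spread of the lone library with the others, gave 0 to 6 higher and 0 to 5 lower. The cause of these differences was not tested. mt-Atp6 passed in 10 of the fits other than the main one and did not in edgeR without the block (adjusted p = 0.281), limma without trend (0.998), quantile normalization (0.883) or, also without the block, with a library left out. Bdh1 passed in none, and its mean log2 ratio was 6.55 with a pseudocount of 0.1, since the IgG libraries are at 0.

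List medians averaged over the pairs moved, with the cause not tested, to -0.25 (lipolysis), -0.29 (lipogenesis), -0.17 (skeletal muscle) and -0.40 (liver) when centred, to 2.40 (macrophage), 1.93 (lymphocyte), -2.53 (Schwann cell) and 0.71 (liver) with a pseudocount of 0.1, and to -0.53 (lymphocyte) with a minimum of 5 scaled CPM. With the nearest-level draw, percentiles entered the top 2.5% for ketone body genes in the first pair (97.53) and for adipocyte markers (97.59) and glycolysis (97.55) in the WT4 pair, and the other lists kept their side. Of 47 named genes 2-fold the same way in both pairs, Igf1 turned to 0.36 in FPKM, and 20 fell short of the 4-fold line. The others that left the 2-fold line in at least 1 pair numbered 11 with quantile normalization, 7 in FPKM, 5 when centred, 4 with TMM factors and 1 with total fragments. The WT4 IgG library held the fewest fragments, with a median of 19 per detected gene, against 25 in the WT4 IP library. Fewer fragments alone are argued against below as the cause of its undetected genes.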

Other observations

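In this part, the tests of fragments per molecule, of lost estimates, of shared loci, of the mt-Atp6 locus in the WT4 pair, of dropped mitochondrial counts and of the nuclear copy were chosen after the result was seen, and the 4 lists of the last paragraph were picked after their percentiles were seen. The mitochondrially encoded genes, as shares of mt-Co1, stood further apart between pairs than between IP and IgG, a comparison picked after the values were seen. The mean log2 gap was larger between pairs for all 10 with fragments in every library, and for 7 of them both gaps between pairs exceeded both between IP and IgG, with mt-Atp6, mt-Nd2 and mt-Nd4 the others. mt-Nd6, from the light strand, stood at 3.07% and 1.096% of mt-Co1 in the first pair's IP and IgG libraries and at 34.2% and 27.0% in those of the WT4 pair. mt-Nd5 stood at 68.9% and 67.1%, then 164.6% and 208.7%. mt-Cytb stood at 78.8% and 66.5%, then 10.5% and 15.1%, and mt-Nd4 at 35.0% and 30%, then 24.6% and 26.7%. The spread within a pair has no replicate here, and no explanation was tested.

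Genes with IP fragments and no IgG fragments, Bdh1 among them, numbered 1043 in the first pair, 8642 in the WT4 pair and 562 in both, and those with IgG fragments alone 2847, 279 and 39. Fewer fragments alone are argued against, since the WT4 IP library thinned to the WT4 IgG total still detected 1.67 times as many genes, and so are fragments lost between genes that share a locus (-0.37 percentage points more at 0, 95% interval -1.85 to 1.11), and recovery of the same transcripts in both pairs is not seen for these genes as a set, as the 562 were 1.04 times the median of shuffles within like IP levels (498 to 577). A candidate explanation is that libraries held few distinct molecules, each sequenced several times: the WT4 IgG library had 14.3 fragments per estimated molecule at genes of 1 to 10 scaled CPM, within 1.06 times from 1 to 200, and the first IP, first IgG and WT4 IP libraries had 50.2, 33.0 and 6.83, where the estimate rose with level (43.2 to 169 in the first IP library) and is no fixed number per molecule. Estimates lost in the authors' processing may add to this, since the 15 genes over 200 scaled CPM at 0 in the WT4 IgG library were 15.2 times the 0.988 that few molecules would leave (interval 8.50 to 25.0), a number that takes IgG levels to follow the other libraries. On the fragments per molecule above, Bdh1's 27 and 31 IP fragments come to 0.538 and 4.54 molecules, values not to be read as counts. Of 383 genes with IP fragments like those of Bdh1, 18 were at 0 in both IgG libraries, or 4.70% (exact 95% interval 2.81 to 7.33). That value lies under the 5% set beforehand as speaking against chance, and it was first read so. The interval was brought in after the value had been seen, and it spans 5%. Chance absence of Bdh1 can therefore not be told apart from recovery with the antibody.

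mt-Atp6 passed the test in IP against IgG, with levels of 55.8%, 2.55%, 1.15% and 0.0123% of mt-Co1 in the first IP, first IgG, WT4 IP and WT4 IgG libraries. In the first pair fragments moved within its locus are argued against, since the summed locus had 2.44 times the IP over IgG ratio of the other mitochondrial genes, while in the WT4 pair that ratio was 0.995, with mt-Atp6 at 4.40% of the locus in IP, too little for the sum to show a move, so this stays open there. Reads shared with a copy of the region on chromosome 1 may account for it: mt-Atp6 and its copy were 100% identical, and 5 other genes with a full copy or within the copied stretch (mt-Atp8, which has no copy entry of its own) stayed at or below 1.91% of mt-Co1, while 4 heavy-strand genes outside it lay at or above 10.5%, which does not say why the first IP library alone kept a high mt-Atp6 count. Whether counts of single mitochondrial genes were dropped in single libraries was tested on other heavy-strand genes with at least 100 fragments in some library. Among these the test cannot decide, since it took the widest spread over all libraries and so counts a shift between pairs as well. The widest spread, of mt-Nd4l, was 9.76-fold (interval 3.86 to 55.4, with 3 fragments in the WT4 IgG library). mt-Nd4l stood at 0.380% and 0.421% of mt-Co1 in the first pair's IP and IgG libraries. In those of the WT4 pair it stood at 0.0434% and 0.0370%, low in both. That test's 10-fold line was first read without an interval, which had spoken against the explanation. The minimum left out mt-Co2, with 57 fragments in the WT4 IgG library (0.704% of mt-Co1) and 0 in the others. In the first IP library mt-Co1 had 120042 fragments, against 8101 in the WT4 IgG library. Counting error alone does not account for that gap of mt-Co2.

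Fatty acid oxidation, respiratory chain, ribosomal protein and tricarboxylic acid cycle genes stood high in IP over IgG in the WT4 pair and not in the first. Matched also on transcript length, the lowest of the 4 percentiles was 96.8 and 3 lists stayed in the top 2.5%. Matched on GC content the lowest was 99.4, and matched on level in the first pair alone it was 98.2, so these 3 explanations are argued against as the whole cause. With 1 library per group, lost estimates in the WT4 IgG library and a difference in the tissue between pairs may both remain, and neither was tested on these lists.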
